A study of Mus musculus with 11 samples.

How the data were processed

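Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map 4 cohesin subunits in mouse embryonic fibroblasts (MEFs), primary cells grown from embryos at embryonic day 12.5. The cells were wild type or SA1-null and were untreated, per the labels' protocols. The antibodies were directed against SA1, SA2, SMC1 and SMC3. Fragments of 100 to 200 bp were cut from a gel, libraries were amplified with 14 PCR cycles, and sequencing was done on a Genome Analyzer IIx, per the labels' protocols. The labels list 11 samples, of which 9 are immunoprecipitations and 2 are input DNA pooled over both genotypes.

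The authors deposited 10 interval lists, each with 3 columns that hold a chromosome, a start and an end. No list gives a score, height, fold enrichment or p-value. The genome build was mm9 and CASAVA 1.7 was used, per the submitters' processing notes. The aligner and the peak caller are not given in the sources used here. The names the lists were deposited under show that SA1 and SA2 of wild-type cells and SA2 of SA1-null cells were called against one input, while SA1 of SA1-null cells and all SMC1 and SMC3 libraries were called against the other. The same names give a false discovery rate of 10, read here as percent, with no minimum fold enrichment. They also give 2 replicates together for the SA1-null SMC1 list. Every other list stands for 1 library. The 2 input libraries have lists of their own, and how these were made is not given in the sources used here. The last peak on chromosome 1 ends at 197068330, beyond the last gene of chromosome 1 in a GRCm38.p6 gene table, and the same held on 10 of the 20 chromosomes. The lists were therefore taken as mm9, as the notes say. Starts were read as 0-based and are printed as 1-based.

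Sequencing depth was not in the lists and is unknown here. The number of peaks in a list depends on depth, on the enrichment reached and on the input used, so list lengths are comparable between genotypes only with that limit. The labels give 1 sample per group except for SMC1 in SA1-null cells, whose 2 samples share 1 list. Nothing in the labels says whether samples came from separate embryos or cultures. No spread between replicates could be measured, and no test between genotypes was made. Shares of peaks are given with 95% Wilson intervals, and ratios of peak numbers with exact binomial intervals. These intervals cover the counting of peaks within these lists and nothing else. Odds ratios with Fisher's exact test (two-sided) compare peaks within the lists. Within classes of width they were pooled by the Mantel-Haenszel method. The 5 odds ratios were adjusted together by Benjamini-Hochberg. Peaks are not replicates of a condition, so such a p-value says nothing about other cultures.

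Peaks were counted as shared when they overlapped by at least 1 bp. The share expected by chance was taken from 1000 random placements of each list within its chromosomes, between the first and the last peak of all lists. A second expectation came from 100 draws in which each peak was displaced by 10 to 50 kb, which keeps its neighbourhood. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6. The overlap functions were tested on simulated data, in which 100% of the shared peaks planted among 24000 wild-type SMC1 peaks were recovered. Their counts equalled those of bedtools 2.31.1 for all 100 ordered pairs of lists.

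Groups, comparisons, the minimum overlap and the first set of alternatives were fixed before the data were examined. Alternatives fixed then and run were an overlap of at least 50% of the shorter peak, merging of peaks closer than 1000 bp, and removal of peaks found in the SA1-null SA1 list or in an input list. Alternatives that rank peaks by score could not be run, because the lists hold no score. Peak width was used in their place, as a choice made after the data were seen. Removal of chromosome X, stratification into 10 classes of width and the local displacement were also added then. The rule for named items was to name genes by peaks at their start sites where an annotation of the files' build was at hand, and otherwise the 5 top-ranked positions of each kind by coordinates. An annotation of mm9 was not used here, so promoters and genes were not analysed, and positions are named instead. They were ranked by the mean percentile of their SMC1 and SMC3 peak widths, since no score was given. Overlap with SA1-null SA1 peaks and with the input lists served as the measure of background.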

Results

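Cohesin is a ring-shaped complex that holds sister chromatids together and shapes chromatin loops. Its ring is built from SMC1, SMC3 and a kleisin, and each ring of somatic vertebrate cells carries either SA1 or SA2 (also called STAG1 and STAG2). The design asked where these subunits lie along the genome in wild-type MEFs and in MEFs that lack SA1. The 8 immunoprecipitation lists differed widely in length. Wild-type cells gave 26602 SA1 peaks, 7741 SA2 peaks, 24000 SMC1 peaks and 15564 SMC3 peaks. SA1-null cells gave 177 SA1 peaks, 6352 SA2 peaks, 47003 SMC1 peaks and 34802 SMC3 peaks. The peaks were narrow, with median widths between 463 bp (SA2, wild type) and 748 bp (SA1, SA1-null). The input lists held 436 and 417 intervals. Apart from SMC1 in SA1-null cells, whose list is named as 2 replicates together, each list came from 1 library, and there was no replicate spread against which a difference between genotypes could be tested.

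The SA1 antibody gave almost no peaks in cells without SA1. The SA1-null list held 177 peaks covering 0.206 Mb, against 26602 peaks covering 14.4 Mb in wild-type cells. Of the wild-type SA1 peaks, 12 overlapped an SA1-null SA1 peak, a share of 0.0451% (95% Wilson interval 0.0258 to 0.0788%). Random placement gave 0.00826% ± 0.00581 (SD over 1000 placements). In the widest 50% of each list the share was 0.00752%, 1 of 13301 peaks. Of the 177 peaks, 99 (55.9%) lay on chromosome X, and 51 of these lay in a single stretch of chromosome X between 120112217 and 121321865. In the input that had served for the SA lists, 99 of the 177 peaks (55.9%, interval 48.6 to 63.0%) had an overlapping interval. In the input against which this list had been called, 15 did (8.47%, interval 5.20 to 13.5%). The wild-type and the SA1-null SA1 lists were called against different inputs.

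In wild-type cells most SA2 peaks lay where SA1 lay, whereas most SA1 peaks had no SA2 peak. Of 7741 SA2 peaks, 5351 overlapped an SA1 peak (69.1%, interval 68.1 to 70.1%), 63.4 times the share under random placement (1.09% ± 0.119, SD). Of 26602 SA1 peaks, 5353 overlapped an SA2 peak (20.1%, interval 19.6 to 20.6%). Displacing the peaks by 10 to 50 kb gave 1.48% for SA2 on SA1 and 0.429% for SA1 on SA2. The SA1 list was the longer one, and depth is unknown, so an SA1 peak without an SA2 peak may not be read as a position without SA2. With the SA1 list shortened by width to the length of the SA2 list, both shares were 33.0%. SMC1, which is part of every ring, had a wild-type peak at 89.1% (interval 88.2 to 89.9%) of the SA2 peaks with SA1. By contrast, 89 of the 2390 SA2 peaks without an SA1 peak had a wild-type SMC1 peak (3.72%, interval 3.04 to 4.56%).

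The ring subunits lay mostly at SA1 positions in wild-type cells. An SA1 peak was present at 72.5% (interval 71.9 to 73.1%) of SMC1 peaks and at 85.4% (interval 84.9 to 86.0%) of SMC3 peaks. An SA2 peak was present at 20.2% of SMC1 peaks and 26.9% of SMC3 peaks. Positions with SA2 and no SA1 were rare, at 89 SMC1 peaks (0.371%) and 48 SMC3 peaks (0.308%). Neither SA protein had a peak at 6512 SMC1 peaks (27.1%) and at 2222 SMC3 peaks (14.3%). The lists of the 2 ring subunits were nested, in that 93.7% (interval 93.3 to 94.1%) of SMC3 peaks overlapped an SMC1 peak and 60.7% of SMC1 peaks overlapped an SMC3 peak.

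SA1-null cells gave longer SMC1 and SMC3 lists than wild-type cells and a shorter SA2 list. The SA1-null SMC1 list held 1.96 times as many peaks as the wild-type list (exact binomial interval 1.93 to 1.99). For SMC3 the ratio was 2.24 (interval 2.19 to 2.28), and for SA2 it was 0.821 (interval 0.794 to 0.848). On each of the 19 autosomes the SMC1 ratio was above 1, from 1.82 to 2.17, and so was the SMC3 ratio, from 1.99 to 2.37. The SA2 ratio was below 1 on all 19, from 0.701 to 0.992. Covered length differed in the same directions, from 14.1 to 26.8 Mb for SMC1, from 8.79 to 23.7 Mb for SMC3 and from 3.69 to 3.43 Mb for SA2. The lower SA2 peak number came from peaks without a wild-type SA1 peak, 2390 in wild-type and 599 in SA1-null cells. SA2 peaks with one numbered 5351 and 5753 in that order. Median widths also differed between the genotypes, with 463 bp in wild-type and 528 bp in SA1-null cells for SA2, 579 and 535 bp for SMC1, and 563 and 652 bp for SMC3. Among peaks wider than the joint median of both lists the ratios were 1.25 for SA2, a reversal, 1.56 for SMC1 and 4.10 for SMC3, which the difference in width moves whatever the peak number. Since depth is unknown and the SA1-null SMC1 list takes 2 replicates together, these ratios compare lists and not amounts of bound cohesin.

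**Figure D1:**
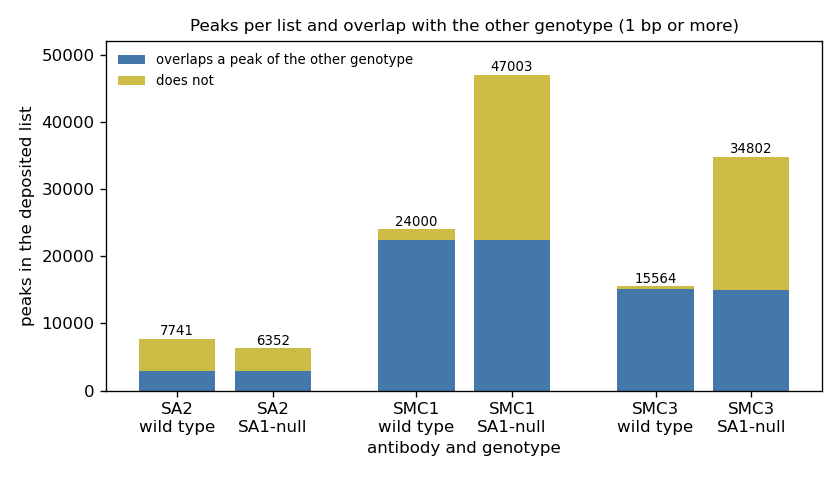
Stacked bars give the number of peaks in each deposited list for SA2, SMC1 and SMC3 in wild-type and SA1-null cells, divided by whether a peak overlapped a peak of the same antibody in the other genotype by 1 bp or more. The SMC1 and SMC3 bars of SA1-null cells hold 24533 and 19811 peaks without a wild-type partner, while 1593 and 506 wild-type peaks had no SA1-null partner.

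Nearly all SMC1 and SMC3 positions of wild-type cells were also called in SA1-null cells. For SMC1, 22407 of 24000 wild-type peaks had an SA1-null SMC1 peak (93.4%, interval 93.0 to 93.7%), against 2.20% ± 0.0982 (SD) under random placement. For SMC3, 15058 of 15564 did (96.7%, interval 96.5 to 97.0%), against 1.76% ± 0.110. A set of 14359 wild-type SMC3 peaks (92.3%) was present in all 4 SMC lists, and 88.9% of these had a wild-type SA1 peak. SA2 positions were shared far less, with 2885 of 7741 wild-type SA2 peaks called in SA1-null cells (37.3%, interval 36.2 to 38.4%). In the other direction, 47.8% of SA1-null SMC1 peaks, 43.1% of SA1-null SMC3 peaks and 45.4% of SA1-null SA2 peaks had a wild-type peak of the same antibody. With the lists brought to equal length by peak width, 61.4% of wild-type SMC1 peaks, 59.5% of wild-type SMC3 peaks and 39.2% of wild-type SA2 peaks had a partner.

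Wild-type SMC1 and SMC3 peaks at SA1 positions were called in SA1-null cells more often than those without SA1. For SMC1, 98.1% (interval 97.8 to 98.3%) of the 17399 peaks with SA1 had an SA1-null SMC1 peak, and 81.0% (interval 80.0 to 81.9%) of the 6601 peaks without SA1 did. The odds ratio was 11.8 (95% interval 10.5 to 13.4). For SMC3 the shares were 98.9% of 13294 and 84.2% of 2270, with an odds ratio of 16.8 (interval 13.8 to 20.5; Fisher's exact test over peaks, two-sided, p = 1.2e-189, and 1.2e-189 after Benjamini-Hochberg adjustment over 5 odds ratios). The other p-values were too small to be computed. Where SA1 and SA2 were both present, the share was 99.3% for SMC1 and 99.6% for SMC3. The few peaks with SA2 and no SA1 gave 94.4% of 89 for SMC1 and 100% of 48 for SMC3 (interval 92.6 to 100%). Peaks with SA1 were also wider, with a median of 597 against 529 bp for SMC1. Within 10 classes of peak width the odds ratios were 8.49 for SMC1 and 11.0 for SMC3, and among the widest 50% of each list they were 1.93 and 2.04. In all, 6.64% of wild-type SMC1 peaks and 3.25% of SMC3 peaks had no SA1-null partner, both under the stated false discovery rate of 10%. The lists hold no heights, so false or weak calls among the peaks without SA1 could not be set apart from SA1 itself.

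**Figure D2:**
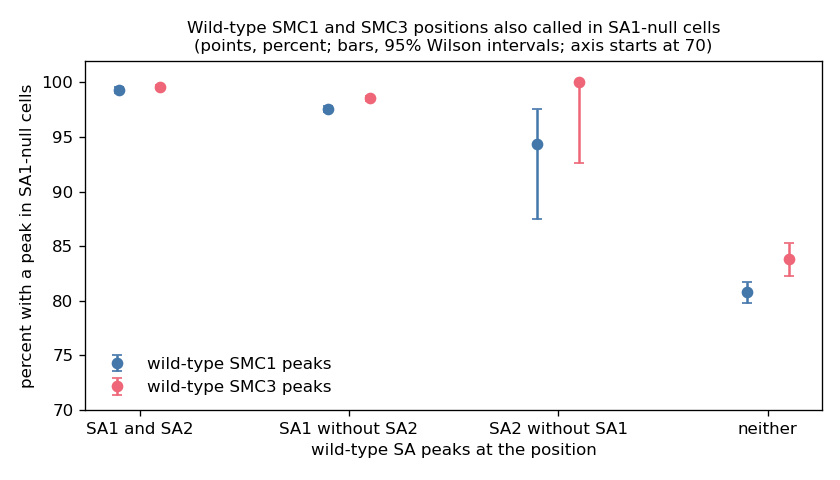
Points give the percent of wild-type SMC1 and SMC3 peaks that had a peak of the same antibody in SA1-null cells, by which SA protein had a wild-type peak at the position, and bars are 95% Wilson intervals covering peak counts only. The classes with SA1 lie at 97.6% or higher, and the class with neither SA protein lies at 80.8% for SMC1 and 83.8% for SMC3.

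The SMC1 and SMC3 peaks called in SA1-null cells alone lay mostly away from wild-type SA1 peaks. Of 24533 SMC1 peaks without a wild-type SMC1 partner, 4272 overlapped a wild-type SA1 peak (17.4%, interval 16.9 to 17.9%), against 76.1% of those with a partner. Of 19811 such SMC3 peaks, 6880 did (34.7%, interval 34.1 to 35.4%), against 87.5% of those with a partner. These shares stood above the random expectation of 1.19% for all SA1-null SMC1 peaks and 1.30% for all SA1-null SMC3 peaks. SA2 peaks of SA1-null cells were present at 1.19% of the SMC1 peaks without a partner and 3.93% of the SMC3 peaks without one. They were present at 23.6% and 31.5% of those with a partner. The SA1-null SA2 list held 6352 peaks, against 47003 for SMC1 and 34802 for SMC3, and depth is unknown. An SMC peak without an SA2 peak may therefore not be read as a position without SA2. Of the unpartnered SMC3 peaks, 80.8% overlapped some SA1-null SMC1 peak and 46.7% (interval 46.0 to 47.4%) one that was itself unpartnered. For the unpartnered SMC1 peaks the shares in the SA1-null SMC3 list were 41.0% and 38.2% (interval 37.6 to 38.8%). Some wild-type list had a peak at 10118 of the unpartnered SMC3 peaks (51.1%) and at 4673 of the unpartnered SMC1 peaks.

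SMC1 and SMC3 together were called at 9095 positions in SA1-null cells where neither had a wild-type peak, and at 49 positions the other way round. The SA1-null lists held 1.96 (SMC1) and 2.24 (SMC3) times as many peaks, and longer lists give more positions of the first kind. Depth is unknown, so these counts compare lists and not gain and loss of cohesin. Among the 9095, 2403 (26.4%, interval 25.5 to 27.3%) had a wild-type SA1 peak and 164 (1.80%) an SA1-null SA2 peak. Among the 49, 18 (36.7%, interval 24.7 to 50.7%) had a wild-type SA1 peak and 10 (20.4%) an SA1-null SA2 peak. The 5 top-ranked by peak width of the 9095 positions called in SA1-null cells alone were on chromosome 6 from 117130075 to 117134564, on chromosome 9 from 70088556 to 70090758, on chromosome 8 from 129356276 to 129358675, on chromosome 2 from 46297950 to 46300033 and on chromosome 11 from 117824104 to 117826104 (mm9). Their SMC3 peaks were 4063, 2004, 1890, 2084 and 1970 bp wide in that order. Those on chromosomes 8 and 2 overlapped a wild-type SA1 peak, and that on chromosome 2 also overlapped SA2 peaks of both genotypes. The 5 top-ranked positions called in wild-type cells alone were on chromosome 5 from 105356451 to 105357708, on chromosome X from 120778032 to 120778888, on chromosome 4 from 107263489 to 107264272, on chromosome 1 from 21030988 to 21031763 and on chromosome 2 from 64010155 to 64010876. None of these 5, unlike 18 of all 49, had a wild-type SA1 peak, that on chromosome X had an SA1-null SA2 peak, and those on chromosomes 5 and X overlapped an interval of an input list or of the SA1-null SA1 list.

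**Figure D3:**
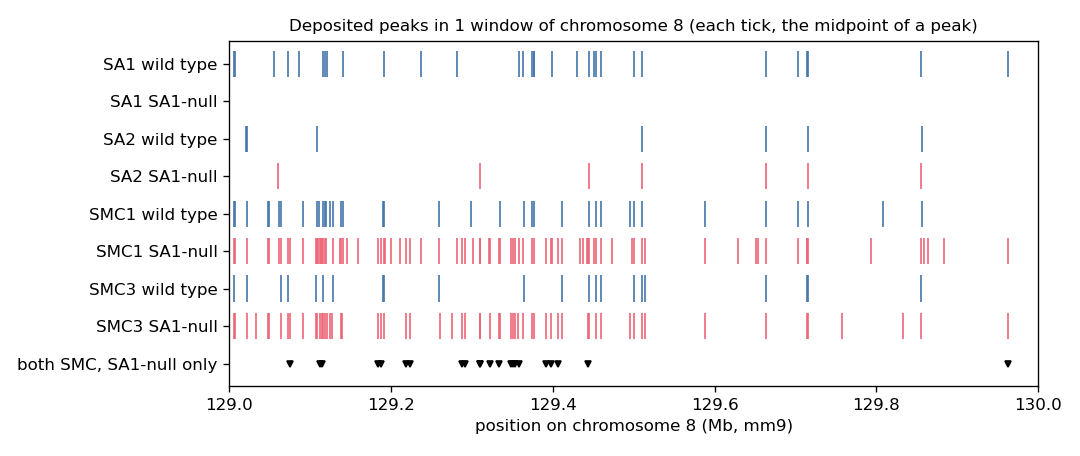
Ticks mark the midpoints of deposited peaks in the 8 lists between 129000001 and 130000000 of chromosome 8 (mm9), with wild-type lists in blue and SA1-null lists in red, and triangles mark positions called for SMC1 and SMC3 in SA1-null cells alone. The window, chosen after the values were seen, holds 38 wild-type and 85 SA1-null SMC1 peaks, 22 wild-type and 62 SA1-null SMC3 peaks, and 22 triangles.

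SA2 peaks of SA1-null cells lay almost entirely where SA1 lay in wild-type cells. Of 6352 such peaks, 5753 overlapped a wild-type SA1 peak (90.6%, interval 89.8 to 91.3%), against 1.16% ± 0.136 (SD) under random placement and 69.1% for wild-type SA2 peaks. Of the 3469 that had no wild-type SA2 peak, 2911 lay at a wild-type SA1 peak (83.9%, interval 82.7 to 85.1%). Of the 2883 that had one, 2842 did (98.6%). With the SA1 list shortened by width to the number of SA2 peaks, which leaves fewer possible partners, the share was 43.0% for all SA1-null SA2 peaks and 22.8% for those without a wild-type SA2 peak. Wild-type SA2 peaks with SA1 were called again in SA1-null cells in 53.1% of cases and those without SA1 in 1.72%. The odds ratio was 65.0 (interval 47.5 to 88.9, Fisher's exact test over peaks) and was not repeated within classes of width. Most SA2 peaks without SA1 had no SMC1 peak either, so false or weak calls among them could not be set apart from SA1 itself. SMC1 accompanied 62.7% of wild-type SA2 peaks and 88.2% of SA1-null SA2 peaks within the same genotype. The wild-type share was 89.1% for SA2 peaks with an SA1 peak and 3.72% for those without one. Against the shorter wild-type SMC1 list, the share of SA1-null SA2 peaks was 84.4%. In SA1-null cells, 11.9% of SMC1 peaks (5604) and 15.8% of SMC3 peaks (5505) had an SA2 peak. In wild-type cells, whose SMC lists were shorter, the shares were 20.2% (4855) and 26.9% (4190).

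The lists were not alike on chromosome X. Wild-type SA1 positions on X were found less often than those on autosomes in each of the other SA2, SMC1 and SMC3 lists. SA2 had a peak at 13.6% (interval 11.3 to 16.2%) of the 765 X positions in wild-type cells, against 20.3% ± 1.99 (SD over 19 autosomes), and at 6.67% (interval 5.11 to 8.66%) in SA1-null cells, against 22.0% ± 1.24. The wild-type SMC3 list covered 31.0% of the X positions and the SA1-null list 66.3%, against autosome means of 50.7% and 75.9%. For SMC1 the X shares were 52.2% and 70.8%, against 66.1% and 80.6%. The labels do not give the sex of the embryos. At the 905 SMC1 positions of SA1-null cells on X, as another reference set, the shares on X differed from those on autosomes in both directions or not at all. The wild-type SA2 list covered 10.6%, against 11.2% ± 1.03 on autosomes, the wild-type SMC1 list 48.7%, against 47.7% ± 1.93, and the SA1-null SMC3 list 66.5%, as on autosomes. Wild-type SA1 was more frequent on X, at 60% against 45.1% ± 1.29, and wild-type SMC3 less, at 28.8% against 32.4% ± 1.31. SA1-null SA2 was low in this set too, at 5.41% (interval 4.12 to 7.09%) against 12.0% ± 0.530. Along X, in 4 parts with equal numbers of wild-type SA1 positions to within 1, SA2 was at 10.5% to 17.7% of them in wild-type cells and at 5.76% to 8.38% in SA1-null cells.

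**Figure D4:**
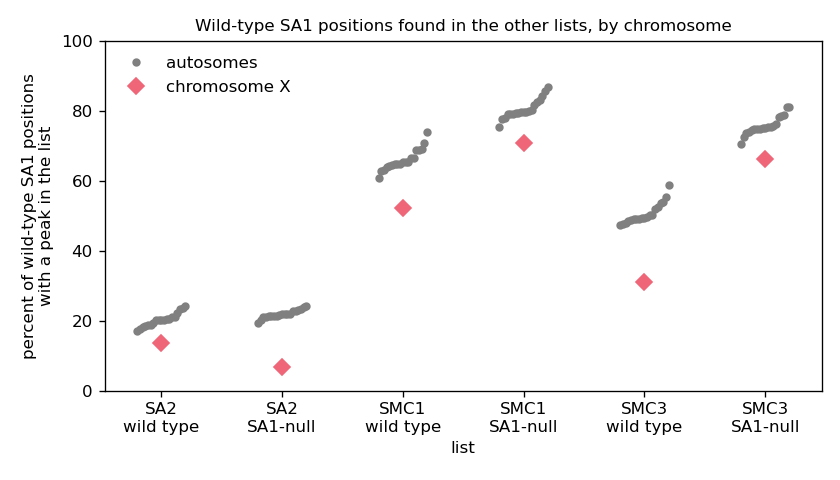
Each point is the percent of wild-type SA1 positions on a chromosome that had a peak in the list named below it, with 19 autosomes in grey, sorted by value, and chromosome X as a red diamond. Chromosome X lies below the lowest autosome in all 6 lists at these positions, and lowest at 6.67% for SA2 in SA1-null cells, whereas at SA1-null SMC1 positions, which are not drawn, the share for wild-type SA2 was 10.6% on X and 11.2% on autosomes.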

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

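The tests of explanations in this part were chosen only after the results were seen. Over the whole lists, the difference in peak number ran in opposite directions between antibodies. The ratio of SA1-null to wild-type peaks was 0.821 for SA2, 1.96 for SMC1 and 2.24 for SMC3. The lower SA2 number came from peaks without a wild-type SA1 peak, 2390 in wild-type and 599 in SA1-null cells. SA2 peaks with a wild-type SA1 peak numbered 5351 in wild-type and 5753 in SA1-null cells. At SA1 positions SA2 therefore did not run against SMC1 and SMC3. Among peaks wider than the joint median of each antibody's lists the ratios were 1.25, 1.56 and 4.10, but widths differed between the genotypes (463 and 528 bp in the median for SA2), so these ratios say little about peak number. With 1 list per group the difference between antibodies was not tested.

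Of the extra SMC1 and SMC3 peaks in SA1-null cells, at most 0.0707% lay in the input and SA1-null SA1 lists, with 1030 intervals in all. The SA1-null SA1 library, called against the same input as the SMC libraries, gave 177 peaks. Lists this short could not hold most of the extra peaks, so a low share was fixed in advance. It cannot decide on regions enriched without antibody, which stay open as a source, also because depth is unknown. For SMC1, whose SA1-null list takes 2 replicates together, an effect of this stays open as well. Of the unpartnered SMC1 peaks, 41.0% lay in the SA1-null SMC3 list. This was between the 94.6% of partnered peaks and the 3.51% that local displacement gave for all SA1-null SMC1 peaks. A more sensitive SA1-null assay, through depth or enrichment, may account for part: wild-type SA1 positions, which were called without the SMC libraries, were found more often in the SA1-null lists, by 14.8 percentage points for SMC1 and 25.6 for SMC3, though a gain of cohesin there would look alike. At the remaining positions sensitivity and a change that follows loss of SA1 cannot be told apart, because the lists hold no heights and width points both ways: a wild-type partner was present for 57.8% of the widest 10% of SA1-null SMC1 peaks, above the 19.4% of the narrowest 10% and below the 68.3% of the eighth of 10 width classes.

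An input list, which is not among the antibody measurements, shared positions with the SA1-null SA1 list. Of the SA1-null SA1 peaks, 55.9% overlapped an interval of the input list that had served for the other SA libraries, and 8.47% overlapped the input list of their own set. On chromosome X the counts were 65 and 4 of 99 peaks.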

How the results depend on the processing

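The widths, equal lengths and chromosome X settings were added after the data were seen; the others were planned. Of 75 alternative values for 16 results, 47 stayed within the interval or on the same side of the test, 27 moved and 1 reversed. Requiring an overlap of 50% of the shorter peak, or leaving out chromosome X, moved no result beyond its interval. The odds ratios by SA1 stayed above 1 and past the test's threshold in every setting run, from 1.93 to 12.1 for SMC1 and from 2.04 to 17.5 for SMC3. Merging neighbours changed the peak ratio to 1.88 for SMC1 and 2.16 for SMC3. Among peaks wider than the joint median it was 1.56 for SMC1, 4.10 for SMC3 and, reversed, 1.25 for SA2, ratios which the difference in width between genotypes moves by construction. Removing background peaks moved the SA1-null SA2 share at SA1 positions to 91.5%, and to 85.2% for peaks without wild-type SA2. In the widest 50% of each list, which leaves fewer possible partners, the shares were 0.00752% for SA1 background, 61.7% for SA2 with SA1 and 18.0% for SA1 with SA2. Wild-type peaks then kept were 28.0% (SA2), 78.1% (SMC1) and 79.8% (SMC3). SA1-null peaks with a wild-type partner were 34.2%, 39.9% and 35.6% in that order, and SA1-null SA2 at SA1 positions 78.2% and, without wild-type SA2, 75.1%. At equal length by width, SA2 with SA1 and SA1 with SA2 were both 33.0%. Wild-type peaks kept were 39.2%, 61.4% and 59.5%, SA1-null peaks partnered 39.1%, 61.1% and 59.0%, and SA1-null SA2 at SA1 positions 43.0% and 22.8%. Score-based thresholds and lengths, and all promoter settings, were not run, as scores and an mm9 annotation were not at hand. No replicate could be left out, and no paired analysis was possible because no group but the pooled SMC1 list has more than 1 sample. Depth, which is unknown, limits every statement on peaks without a partner.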

Other observations

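The tests of explanations in this part, and the comparisons with displaced positions, were chosen only after the results were seen. The positions called for SMC1 and SMC3 in SA1-null cells alone lay in regions where wild-type cells had SMC1 peaks. Per 1 Mb window they numbered 3 in the median and 23 at most, on chromosome 13 between 63000001 and 64000000, where wild-type cells had 17 SMC1 and 7 SMC3 peaks and SA1-null cells 56 and 44. Across 2312 windows, which are not independent, their number went with that of wild-type SMC1 peaks (Pearson r = 0.63). Their median distance to the nearest wild-type SMC1 peak was 20.7 kb, against 56.2 kb ± 1.32 (SD) for random positions on the same chromosomes. Positions displaced by 10 to 50 kb, which keep the regional density, gave 22.1 kb ± 0.318 (SD over 100 draws, from 21.2 to 22.8 kb), so most of the difference from random positions went with the region.

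Among SA1-null SMC peaks the share with a wild-type partner did not rise steadily with width. It was highest in the eighth of 10 width classes, at 68.3% for SMC1 and 70% for SMC3, and lower in the widest class, at 57.8% and 45.3%. The unpartnered peaks of the widest class numbered 1982 for SMC1 and 1903 for SMC3. Of these, 72.3% and 94.2% overlapped a peak of the other ring subunit in SA1-null cells, against 6.03% and 8.57% after local displacement. In the narrowest class the shares were 23.5% and 62.6%, against 2.43% and 3.20%. Wild-type SA1 was present at 13.2% and 23.9% of the unpartnered peaks of the widest class.

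Of the wild-type SA2 peaks, 2390 (30.9%) had no SA1 peak, and 1.72% of these were called again with the same antibody in SA1-null cells. Any SMC1 or SMC3 list of either genotype had a peak at 7.41% of these peaks, against 96.8% of SA2 peaks with SA1 and 2.77% ± 0.367 (SD) after local displacement, which is consistent with calls away from cohesin for most of them. The 2213 without any SMC peak exceed the 774 false calls that the stated rate of 10% would allow in 7741 peaks. Of the 2390 peaks, 0.879% lay in the input and SA1-null SA1 lists, which are too short to hold most of them. Regions enriched without antibody may be called in other libraries too, but 1.72% lay in the SA1-null SA2 list and 7.41% in any SMC list. Depth is unknown and the SMC lists were called against the other input, so these shares cannot decide on such regions. SA2 bound without the ring and a false discovery rate above the stated one stay open and were not tested.

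The lower share of SA2 on X in SA1-null cells stood outside the autosomes: at wild-type SA1 positions the log2 ratio of SA1-null to wild-type SA2 shares was -1.03 on X and 0.12 ± 0.15 (SD) over the autosomes, from -0.18 to 0.40, a difference of -1.15. Regions in the input and SA1-null SA1 lists held 3 of the 765 positions on X, and leaving them out gave -1.01, still below the lowest autosome. So few positions could not make up the difference, and leaving them out could hardly change the ratio. This is no test of background regions outside the lists, which stay open. Fewer X copies in all SA1-null cultures would lower SMC1 and SMC3 on X as well, but neither lay below the autosomes. SMC3 lay above the highest autosome on X in the ratio of shares, the odds ratio of shares and the peak number ratio. SMC1 lay above it in the ratio of shares and within the autosomes in the other measures. Its peak number ratio was 1.87 on X and 1.97 ± 0.0762 (SD) over the autosomes. This would argue against fewer X copies only with equal X copies in the wild-type SMC and SA2 cultures, which is unknown. X held 2.60% of wild-type SA2 peaks but 2.02% and 1.78% of wild-type SMC1 and SMC3 peaks. More sensitive SA1-null SMC lists could also hide a fall. A culture with fewer X copies behind the SA1-null SA2 library alone may give this pattern, since the ratio was -0.86 or lower in each of 4 parts of X, on counts as small as 11 against 20 of 191 positions, but any other feature of this library that covers X would do the same, and an effect of SA1 loss was not tested apart from it.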
